A study of Mus musculus with 6 samples.

How the data were processed

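RNA from bone marrow-derived macrophages of 2 genotypes, 3 libraries each, was measured by sequencing. Per the labels' protocols, cDNA was made full-length with a SMART-Seq kit for low input, fragmented with a Nextera XT kit and sequenced on a NextSeq instrument after equimolar pooling. These kits do not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Growth medium held 10% serum, per the labels' protocols.

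The authors deposited raw counts, as whole numbers per Ensembl gene, in a separate table for each library with 49671 genes. Per the submitters' processing notes, the tools were bcl2fastq 2.19.0.316, FastQC 0.11.8, STAR, edgeR 3.30.0 and deepTools 3.5.1, with the mm10 genome build and no role or order stated. The version of STAR, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Genes with near-identical copies (such as the H2-Q, Ifi200, Nlrp1 and Ms4a families) can therefore have lost or gained reads. The tables hold no summary rows, and 5 of 13 mitochondrial protein genes are listed at 0 in all 6 libraries.

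Gene symbols and coordinates were taken from GENCODE mouse release M21, which uses the same build, by Ensembl identifier. Of the identifiers 49412 matched and 259 did not, and the unmatched ones held at most 0.00737% of a library's count. Of 99 named and tested genes, 10 overlap another tested gene in the annotation.

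The total count per library was 17352974, 18366718 and 18360443 in wild type and 17393166, 17404955 and 15895817 in the knockout. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Libraries were compared before averaging: pairs of the same genotype differed by a chi-square of 6.86 to 11.5 per degree of freedom over genes, above sampling noise, and pairs of different genotype by 71.2 to 95.3. No pair was therefore treated as a duplicate.

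Groups were taken from the genotype label. The comparison was knockout against wild type in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood F test with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.0933. Standard errors of log2 fold changes were obtained from the F statistic. CPM values are TMM-normalised and were computed here from the deposited counts.

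Before the data were examined, 25 gene lists were fixed: 4 primary, 12 secondary and 9 of cell type markers. The 23 lists with at least 3 tested genes were tested in 1 Benjamini-Hochberg family with camera of limma 3.58.1 at its preset correlation of 0.01. The same test with an estimated correlation, and fry, served as alternatives. Some list members, among them Eda2r, Nfkb1, S100a8, Mmp8 and Ccl5, and the genes added under other observations were named after their values were seen. The other genes named were set in advance. They were Trp53; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean logCPM of at least 3, a conventional symbol and no overlap between genotypes; the 4 (primary lists) or 3 (other lists) members with the smallest p in each list; and Cdkn1a, Mdm2, Ccng1, Il1b, Il6, Tnf, Cxcl1, Cxcl2, Mki67, Ccnb1, Mcm5, Csf1r and Adgre1. Genes near Trp53 were compared with all others by Fisher's exact test within 10 Mb.

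Alternatives set in advance were DESeq2 size factors, library size alone and upper-quartile factors, no filter and a stricter filter on low counts (1 CPM in 3 libraries and a total of 50), DESeq2 1.42.0 and limma-voom, robust empirical Bayes, the replicate number as a block, each library left out in turn, a minimum fold of 1.5, an adjusted p below 0.01 and windows of 5 and 20 Mb. An offset that removes each library's trend with GC content and transcript length was added after seeing the data. It covered 11863 tested genes.

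The procedure was tested on simulated counts for this comparison with 11750 genes in the step. It recovered 59.1% of genes changed 1.5-fold, 81.8% of those changed 2-fold and 96.9% of those changed 4-fold, and 15 of 171 calls were false. Over 50 simulated lists, camera called the 1 raised list and 0 of the others. Simulated genes were drawn independently, so this step cannot show how often lists of genes that vary together are called falsely. The estimated correlation of the G2/M and mitosis list, for example, was 0.665. With a GC trend added to unchanged genes, the offset lowered the number of calls from 5010 to 2.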

Results

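Messenger RNA was sequenced from mouse bone marrow-derived macrophages that carried intact p53 (wild type) or lacked it (knockout). p53, encoded by Trp53, is a transcription factor that halts the cell cycle or triggers cell death after DNA damage and other stress. Bone marrow-derived macrophages are obtained by growing femoral marrow cells with macrophage colony-stimulating factor (MCSF), here for 7 days at 100 ng/ml. The cells were then held at 5 ng/ml for 48 h, which lets them leave the cell cycle, and returned to 100 ng/ml for 18 h to re-enter it. Each genotype had 3 libraries. The total count per library ran from 15895817 to 18366718, and 16599 to 17317 of 49671 listed genes had at least 1 count. The series concerns clonal blood cells with TP53 mutations and artery disease, and its comparison asks how the absence of p53 alters gene expression in macrophages. The labels do not say whether the 3 libraries of a genotype came from separate animals or cultures, so every p-value measures the spread between these libraries, which may be technical. Levels are given in CPM, counts scaled to the TMM-normalised library size, as mean ± SD with n = 3 per genotype, and log2 fold changes are knockout minus wild type.

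Trp53 transcript was still counted in the knockout, at a lower level. The gene (ENSMUSG00000059552) spans positions 69580359 to 69591873 of chromosome 11 in the mm10 genome. It had 92.1, 106 and 84.7 CPM in the wild-type libraries and 46.6, 47.5 and 52.0 CPM in the knockout libraries. The log2 fold change was -0.95 (SE 0.09, edgeR adjusted p = 4.80e-06). A count per gene does not show which exons the reads came from, so it cannot show whether the deleted part was transcribed and checks the genotype labels only weakly.

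Genes that p53 is known to activate were mostly lower in the knockout. Of 48 p53 target genes fixed in advance, 45 were tested, of which 29 fell, 8 rose and 8 did not pass the threshold; adjusted over the list alone, 29 fell and 10 rose. Phlda3, an inhibitor of Akt signalling on chromosome 1 (135766119 to 135769136), had 49.2 ± 3.92 CPM in wild type and 2 reads in all 3 knockout libraries together against 2608 in wild type. Scaled for library size, the ratio of wild type to knockout was 1268, with a 95% interval of 351 to 10476 that covers counting error only. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090976 to 29100727), fell from 589 ± 39.4 to 196 ± 13.9 CPM, or 3.01-fold. Mdm2, the ubiquitin ligase that degrades p53 (chromosome 10, 117688875 to 117710758), fell from 493 ± 29.7 to 177 ± 4.69 CPM. Ccng1, which encodes cyclin G1 (chromosome 11, 40748552 to 40755311), fell from 347 ± 36.6 to 88.7 ± 7.40 CPM.

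The median log2 fold change of the p53 target genes was -0.52, and all 3 knockout libraries lay below all 3 wild-type libraries in 27 of the 45 genes. The list passed limma's camera test, which compares a list with all other genes (adjusted p = 5.18e-13 over 23 lists; adjusted p = 0.0167 with an estimated correlation between genes). The 8 members that rose, named after their values were seen, were Tap1, Sp100, Pmaip1, Ckap2, Jun, Apaf1, Pidd1 and Plk2. Tap1 encodes a peptide transporter of antigen presentation and Sp100 a nuclear body protein, and both are also known interferon-responsive genes. Their log2 fold changes were 1.35 and 0.77. Eda2r was at 0 in all 3 knockout libraries against 43 reads in wild type, which makes it at least 13.9-fold lower with 3 counts over the group as the floor. At its bound it lies below the list median of -0.52, as Phlda3 does, so the median is the same whichever value is used.

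Across all genes, 2714 rose and 2379 fell in the knockout out of 11882 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Of these, 714 rose and 292 fell by 2-fold or more. All 3 libraries of one genotype lay above all 3 of the other in 52.5% of tested genes, where chance gives 10%. The first principal component held 70.0% of the variance and separated the genotypes. The balance of both directions depended on the scaling: with upper-quartile factors 2259 genes rose and 2965 fell, and with library size alone 3098 rose and 1948 fell.

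Among genes with a mean logCPM of at least 3, a conventional symbol and no overlap between genotypes, the largest rises were those of Ifi206 (log2 fold change 5.55, SE 0.30), Ccl12 (3.92, SE 0.20), H2-Q6 (3.91, SE 0.35), Oasl1 (3.37, SE 0.15) and Cxcl10 (3.29, SE 0.17). Ccl7 (3.23), Ifit3 (3.08), Rsad2 (2.91), Acap1 (2.82) and Ifi44 (2.80) followed. Without wild-type replicate 1 the value of Ifi44 was 3.53. Ifi206, an interferon-inducible nucleic acid sensor family member, went from 0.608 ± 0.235 to 28.5 ± 9.04 CPM. H2-Q6, a non-classical MHC class I gene, went from 2.43 ± 1.30 to 36.8 ± 14.6 CPM. Both have near-identical relatives, and how reads shared between copies were counted is not given in the sources used here, so their values are uncertain.

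Under the same limits on level, symbol and overlap, the genes that fell most after Phlda3 were Rtn4rl1 (log2 fold change -3.86, SE 0.33), Trp53inp1 (-3.70, SE 0.22), Hpgd (-3.51, SE 0.19), Ephx1 (-2.95, SE 0.18) and Nlrp1a (-2.79, SE 0.16). Gsta3 (-2.52), Mgmt (-2.36), Plxdc2 (-2.33) and Lpin1 (-2.21) completed the group. Trp53inp1, a p53-induced stress protein, fell from 71.2 ± 18.1 to 5.44 ± 1.71 CPM. Hpgd, the enzyme that inactivates prostaglandins, fell from 22.8 ± 4.75 to 2.00 ± 0.134 CPM. Ephx1, the microsomal epoxide hydrolase, fell from 47.3 ± 8.71 to 6.10 ± 1.46 CPM. Mgmt, which repairs alkylated guanine in DNA, fell from 14.3 ± 0.621 to 2.79 ± 0.218 CPM. Nlrp1a, an inflammasome sensor gene with close paralogs beside it, shares the uncertainty over shared reads. The edgeR adjusted p of these 20 genes was at most 1.97e-04.

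**Figure D1:**
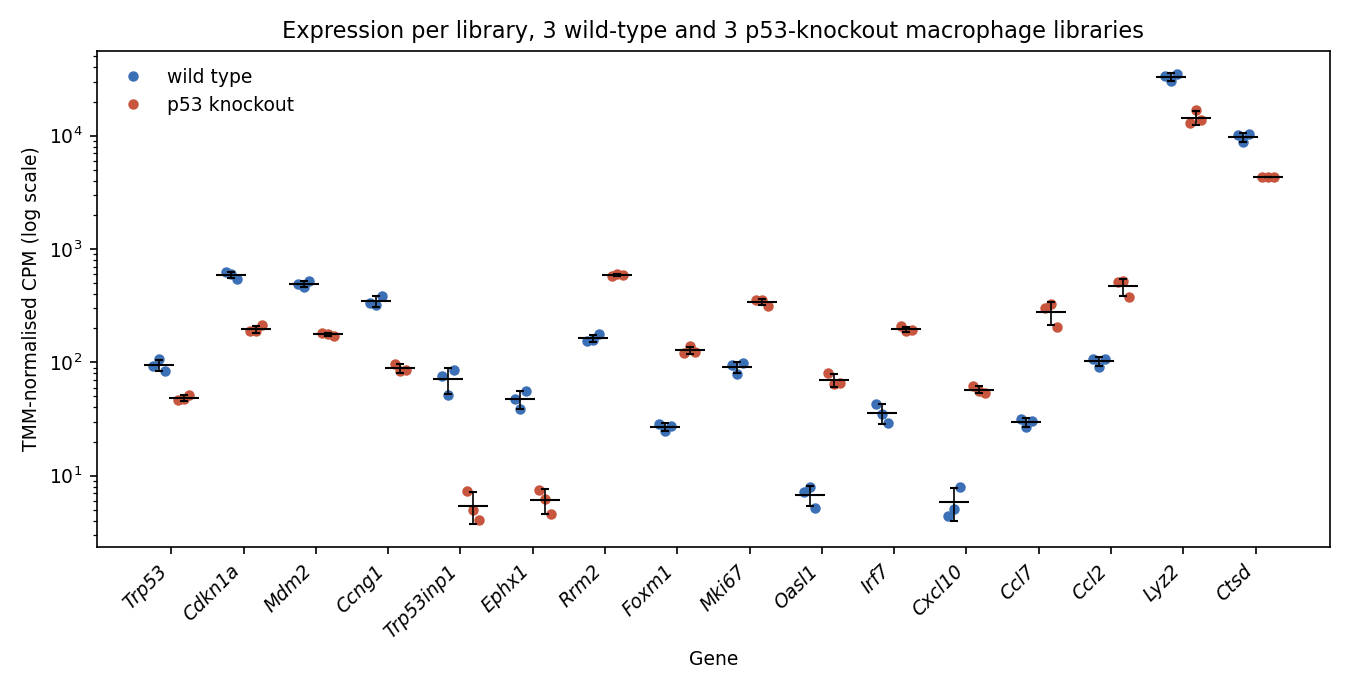
TMM-normalised CPM (vertical log axis) of 16 named genes (horizontal axis) in each of 3 wild-type (blue) and 3 p53-knockout (red) libraries, with horizontal bars for the mean and vertical bars for the SD. The genotypes do not overlap in any of the genes drawn, with Cdkn1a at 589 CPM in wild type and 196 CPM in the knockout, and Ccl7 at 29.6 and 278 CPM. Several of these genes were named under a rule that required no overlap, and named genes that overlap, such as Tnf, are not drawn.

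DNA replication genes rose almost without exception. Of 42 tested, 41 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 fold change of 1.20, or 2.30-fold. Rrm2, a subunit of ribonucleotide reductase (chromosome 12, 24708241 to 24714146), rose from 163 ± 11.9 to 593 ± 11.4 CPM. Mcm10, an initiation factor, rose from 33.2 ± 1.19 to 125 ± 2.96 CPM. Tk1 and Tyms, which supply thymidine nucleotides, rose 3.48-fold and 3.27-fold, and the replicative helicase subunit gene Mcm5 rose 2.53-fold. The list passed camera (adjusted p = 2.03e-56; adjusted p = 0.0167 with an estimated correlation), and the knockout libraries lay above all wild-type libraries in 41 of the 42 genes.

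Genes of the G2 phase and mitosis rose too. All 40 tested rose, also when adjusted over the list alone, with a median log2 fold change of 1.77, or 3.41-fold. Foxm1, the transcription factor that drives mitotic genes (chromosome 6, 128362967 to 128376146), rose from 27.0 ± 2.01 to 128 ± 8.89 CPM. The mitotic kinase genes Aurkb and Aurka rose 3.81-fold and 3.75-fold, and Espl1, which encodes the protease that separates sister chromatids, rose 4.93-fold. Mki67, the proliferation marker Ki-67, rose from 90.7 ± 10.5 to 343 ± 22.2 CPM, and Ccnb1, which encodes cyclin B1, rose from 40.5 ± 12.6 to 135 ± 22.0 CPM. In all 40 genes the knockout libraries lay above the wild-type libraries. The list passed camera at the preset correlation (adjusted p = 9.49e-78) but not with an estimated correlation between genes (adjusted p = 0.0575).

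DNA repair and damage checkpoint genes rose as well. Of 30 tested, 28 rose and 0 fell (29 and 0 adjusted over the list alone), and the median log2 fold change was 1.15. Brca1 and Rad51, both of homologous recombination, rose from 29.8 ± 0.951 to 94.4 ± 6.92 CPM and from 36.2 ± 0.867 to 101 ± 6.05 CPM. H2afx, the histone variant marked at DNA breaks, rose from 19.0 ± 2.04 to 76.2 ± 6.63 CPM. The knockout libraries lay above all wild-type libraries in 29 of the 30 genes, and the list passed camera (adjusted p = 5.54e-26; adjusted p = 0.0167 with an estimated correlation).

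Inflammatory genes rose by very different amounts, with several chemokine genes at the top and Tnf not past the threshold. Of 36 genes on the inflammatory cytokine and NF-kB response list 27 were tested, of which 21 rose, 1 fell and 5 did not pass, with the same counts adjusted over the list alone. The monocyte-attracting chemokine genes Ccl7 (chromosome 11, 82045712 to 82047525), Ccl2 and Ccl12 rose from 29.6 ± 2.48 to 278 ± 62.8 CPM, from 102 ± 9.35 to 468 ± 81.3 CPM and from 1.17 ± 0.264 to 17.8 ± 2.39 CPM. Cxcl10, a chemokine that interferons also induce, rose from 5.84 ± 1.89 to 57.5 ± 4.23 CPM, and Cxcl2 rose from 9.32 ± 1.09 to 18.5 ± 0.651 CPM. Ccl5, named after its value was seen, had the largest log2 fold change of the list, 3.93 (SE 0.41). Il1b, which encodes interleukin-1 beta, rose 2.52-fold at a low level, from 1.46 ± 0.564 to 3.69 ± 0.673 CPM (edgeR adjusted p = 0.00352). Tnf was at 34.6 ± 2.83 and 34.9 ± 0.196 CPM (log2 fold change 0.01, SE 0.09, adjusted p = 0.933).

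Il6 had 0 reads in the wild-type libraries, where a count of 0 allows up to 3, and 9 in the knockout libraries. Cxcl1 had 8 and 22, and neither passed the filter on low counts of the main comparison. The member that fell was Nfkb1, the gene of the NF-kB p105 precursor, with a log2 fold change of -0.42. The list median was 0.52, and the knockout libraries lay above all wild-type libraries in 20 of 27 genes. The list passed camera (adjusted p = 1.57e-10; adjusted p = 0.0167 with an estimated correlation). Of 9 tested neutrophil markers 5 also rose and 2 fell, and that list did not pass camera (adjusted p = 0.135). S100a8 rose from 1.65 to 3.70 CPM and Ltf from 0.190 to 8.55 CPM, while Csf3r and Mmp8 fell.

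**Figure D2:**
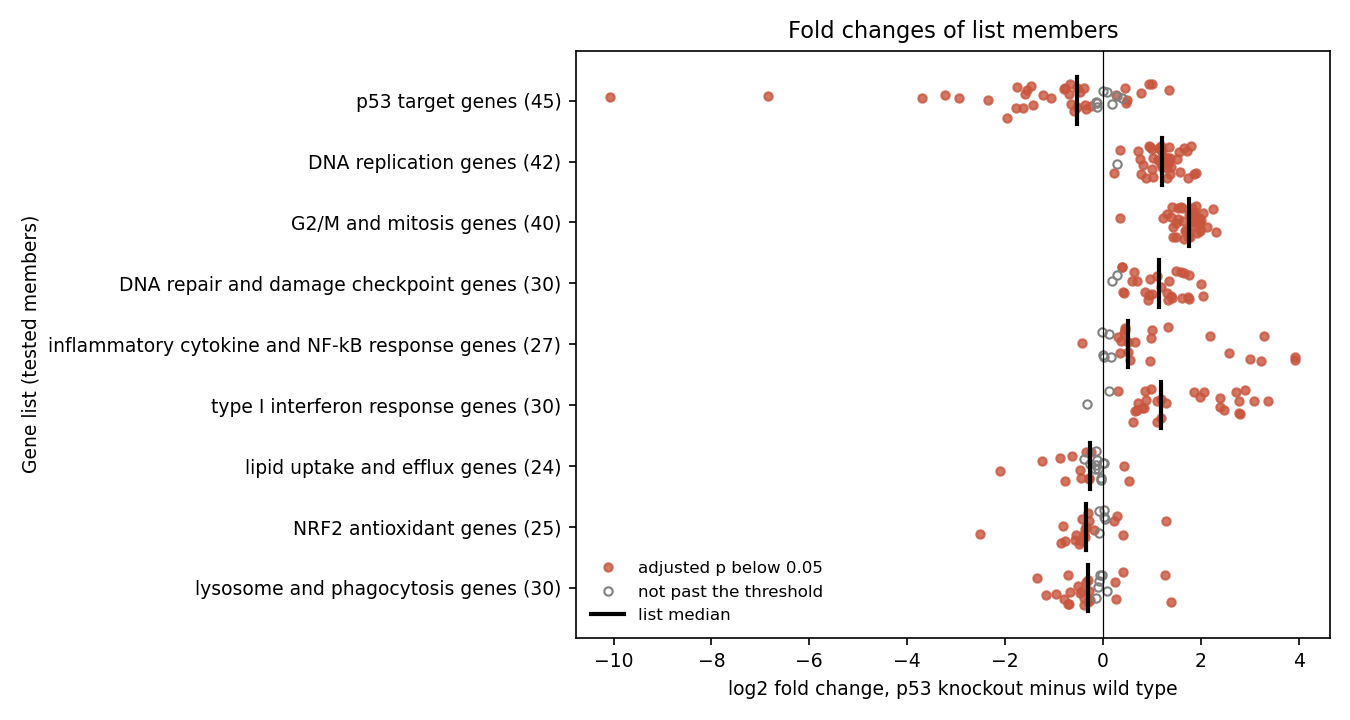
Fold changes of the tested members of 9 gene lists (vertical axis, tested members in brackets) as log2 knockout minus wild type (horizontal axis), with filled points for genes past an edgeR adjusted p of 0.05, open grey points for the rest and a black bar at each list's median. The G2 and mitosis list has its median at 1.77 and the p53 target list at -0.52, and the p53 target points left of -6 are Phlda3 and Eda2r, whose fitted values depend on the prior count because the knockout libraries hold 2 and 0 reads.

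Type I interferon response genes rose together. Of 30 tested, 28 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 1.18, or 2.27-fold. Oasl1, an antiviral gene of the oligoadenylate synthetase family (chromosome 5, 114923240 to 114937915), rose from 6.75 ± 1.40 to 69.9 ± 8.68 CPM. Cmpk2, a mitochondrial nucleotide kinase gene, rose 6.88-fold to 77.2 ± 9.56 CPM, and Irf7, a transcription factor of the interferon response, rose from 35.6 ± 7.05 to 197 ± 9.83 CPM. In 28 of the 30 genes the knockout libraries lay above all wild-type libraries. The list passed camera at the preset correlation (adjusted p = 7.40e-37), and the call was lost with an estimated correlation (adjusted p = 0.0718).

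Lysosomal, antioxidant and lipid-handling genes were lower on balance. On the lysosome and phagocytosis list 19 of 30 tested genes fell and 5 rose (20 and 5 adjusted over the list alone), with a median log2 fold change of -0.30. Ctsd, which encodes the protease cathepsin D (chromosome 7, 142375911 to 142388038), fell from 9700 ± 863 to 4327 ± 27.3 CPM, and Tyrobp, a receptor adaptor gene, fell 1.65-fold from 1265 ± 28.7 CPM. Fcgr1, the high-affinity IgG receptor gene, went the other way, from 50.3 ± 1.57 to 121 ± 7.43 CPM. Of 25 NRF2 antioxidant genes 16 fell and 4 rose, over all genes and over the list alone, with a median of -0.35. Gsta3, a glutathione transferase gene, fell 5.74-fold, Cat, which encodes catalase, fell 1.82-fold, and Taldo1, of the pentose phosphate pathway, fell 1.47-fold. The cystine transporter gene Slc7a11 had the largest rise of the list, with a log2 fold change of 1.28.

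On the lipid uptake and efflux list 11 of 24 tested genes fell and 2 rose, over all genes and over the list alone, with a median of -0.26. Cd5l, a secreted macrophage protein gene, fell from 538 ± 91.4 to 125 ± 13.8 CPM. Lipa, the lysosomal acid lipase gene, fell 1.54-fold, and Mylip, which directs degradation of the LDL receptor, fell 2.37-fold. These 3 lists passed camera at the preset correlation (lysosome adjusted p = 2.97e-05, NRF2 adjusted p = 5.68e-05, lipid adjusted p = 2.86e-04). With an estimated correlation the calls were lost (adjusted p = 0.0939, adjusted p = 0.126 and adjusted p = 0.162). At the preset correlation 5 of 12 secondary lists passed.

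The other secondary lists did not pass camera with all 6 libraries and the filter on low counts, although single genes on them did. Of 24 glycolysis genes 12 rose and 5 fell (adjusted p = 0.153), among them the lactate exporter gene Slc16a3 (log2 fold change 0.84), the lactate dehydrogenase gene Ldha (0.62) and Tpi1 (0.62). The glycolysis list passed camera without wild-type replicate 2 (adjusted p = 0.00735) and without the filter on low counts (adjusted p = 0.0298), and its adjusted p was 0.735 with an estimated correlation. Of 29 nuclear-encoded oxidative phosphorylation genes 4 rose and 6 fell (3 and 6 adjusted over the list alone, adjusted p = 0.597), with Ndufa4 at -0.41, Uqcrh at -0.44 and Cycs at 0.42. Of 28 unfolded protein and integrated stress response genes 9 rose and 6 fell (adjusted p = 0.925). Among these were Psat1, of serine synthesis (1.32), the cystine transporter gene Slc7a11 (1.28), also on the NRF2 list, and Sesn2 (-1.07), which is also a p53 target. Of 24 cholesterol biosynthesis genes 1 rose and 6 fell (adjusted p = 0.379), with Tm7sf2 at -0.998, Msmo1 at -0.56 and Sc5d at -0.52. The median of that list, 0.02, had the opposite sign to its mean, -0.08, and to its test.

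Of 12 tested alternative activation genes 2 rose and 1 fell (adjusted p = 0.298). The mannose receptor gene Mrc1 rose from 29.0 ± 4.59 to 80.8 ± 7.88 CPM, Chil3 rose from 0.206 ± 0.0823 to 3.95 ± 0.861 CPM, and the haemoglobin scavenger receptor gene Cd163 fell from 10.1 ± 1.53 to 5.28 ± 1.41 CPM. Of 18 NADPH oxidase and integrin adhesion genes 1 rose and 6 fell (adjusted p = 0.153), with Ncf1 at -0.67, Itgav at -0.69 and Icam2 at 1.01. Of 13 MHC class II presentation genes 3 rose and 3 fell (adjusted p = 0.998), with Cd74 at 0.80, the costimulatory ligand gene Cd86 at 1.14 and H2-DMb1 at -0.66. The median of that list was -0.01, while its mean was 0.07 and its test pointed up. Except where given, the counts adjusted over the list alone were the same for the lists of this and the preceding paragraph.

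Macrophage markers stayed abundant in both genotypes, with changes in both directions. Of 19 tested 4 rose and 8 fell (camera adjusted p = 0.128). The list passed, with its test pointing down, without knockout replicate 2 (adjusted p = 0.0403) and without the filter on low counts (adjusted p = 0.0334). The MCSF receptor gene Csf1r had 3913 ± 99.9 and 4261 ± 70.2 CPM (log2 fold change 0.12, SE 0.06, edgeR adjusted p = 0.0951), and Adgre1, which encodes F4/80, fell from 2143 ± 153 to 1375 ± 44.6 CPM. Lyz2, the lysozyme gene, fell 2.29-fold (edgeR adjusted p = 9.81e-07), from 3.24 ± 0.227% to 1.47 ± 0.206% of all counts (exact permutation test of the share, two-sided p = 0.1, the smallest that 3 against 3 allows). The fractalkine receptor gene Cx3cr1 fell 1.89-fold and Fcgr1 rose 2.40-fold. The 10 most counted genes took 12.1 ± 0.291% of counts in wild type and 9.23 ± 0.323% in the knockout.

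No list of markers of other cell types passed camera with all 6 libraries and the filter on low counts. Of 9 tested neutrophil markers 5 rose and 2 fell (5 and 3 adjusted over the list alone, adjusted p = 0.135): the granule genes Ltf and Ngp rose to 8.55 ± 2.70 and 6.78 ± 1.42 CPM, and Csf3r fell from 38.0 ± 6.65 to 18.2 ± 0.194 CPM. The list passed without wild-type replicate 1 (adjusted p = 0.0378) and without the filter (adjusted p = 0.0120). Of 5 monocyte and progenitor markers 1 rose and 1 fell (1 and 2 adjusted over the list alone, adjusted p = 0.597), with Cebpe at 2.81, Cd34 at -0.59 and F13a1 at -0.87 (edgeR adjusted p = 0.0528). The median of that list was -0.50 and its mean 0.15. Of 4 dendritic cell markers 2 rose (adjusted p = 0.298), namely Bst2, also an interferon response gene (0.65), and Batf3 (1.85), with Itgax at -0.17. Of 10 osteoclast markers 3 rose and 1 fell (adjusted p = 0.891), with Acp5 at 2.13, Mmp9 at 2.15 and Atp6v0d2 at -2.07.

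Of 3 lymphoid markers 1 fell (adjusted p = 0.175): Ighm, the immunoglobulin mu chain gene, went from 10.9 ± 3.24 to 0.691 ± 0.201 CPM, with Lck at 1.16 (edgeR adjusted p = 0.169) and Cd79b at -0.11 (edgeR adjusted p = 0.794). Lck was at 1.98 without wild-type replicate 2 and 0.55 without knockout replicate 1, and passed in neither. Of 3 stromal and endothelial markers 1 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.153), with the receptor gene Kdr at 2.26, Kitl at -0.47 and Acta2 at 0.91 (edgeR adjusted p = 0.0671). The mast cell list had 2 tested genes, Gata2 (1.66) and Siglecf (-0.45), and the erythroid and megakaryocyte list also 2, Pf4 (0.75) and Ppbp (1.68), too few for the list test. Of the 7 marker lists tested, camera called 0 at an adjusted p below 0.05 and 0 at an unadjusted p below 0.05. The fry test of limma, which does not compare a list with other genes, called 6 of them. Where no other count is given, the counts adjusted over the list alone were the same for the marker lists.

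Every library carried transcripts of the Y chromosome and none of Xist, the RNA of the inactive X chromosome, whose count of 0 allows up to 0.186 CPM in the smallest library. Ddx3y had 111 ± 5.59 CPM in wild type and 84.6 ± 5.20 CPM in the knockout, Uty had 51.8 ± 3.36 and 41.0 ± 0.787 CPM, Eif2s3y had 75.3 ± 7.44 and 64.0 ± 5.08 CPM, and Kdm5d had 27.1 ± 1.13 and 21.6 ± 0.773 CPM. Ddx3y, Uty and Kdm5d fell, with log2 fold changes of -0.39, -0.34 and -0.33 (edgeR adjusted p = 9.60e-04, 0.00492 and 0.0174), and Eif2s3y was at -0.23 (edgeR adjusted p = 0.0537).

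Genes close to Trp53 were compared with all others, since a knockout allele can carry neighbouring DNA of another strain. Within 10 Mb on chromosome 11, 120 of 251 tested genes passed the threshold (47.8%), against 42.8% elsewhere (odds ratio 1.23, 95% interval 0.947 to 1.59, two-sided Fisher's exact test p = 0.122). Within 5 Mb the odds ratio was 1.41 (Fisher's exact test p = 0.0701) and within 20 Mb 1.21 (Fisher's exact test p = 0.0552). Without the filter on low counts the 10 Mb odds ratio was 1.39 (Fisher's exact test p = 0.00297). Nlrp1a, Rtn4rl1, Acap1 and Aurkb lie in the 10 Mb window. Ccl2, Ccl7 and Ccl12 lie beyond it but within 20 Mb, each 12.5 Mb from Trp53, and Ccl5 lies 13.9 Mb from it. The position of these chemokine genes therefore does not exclude flanking DNA.

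**Figure D3:**
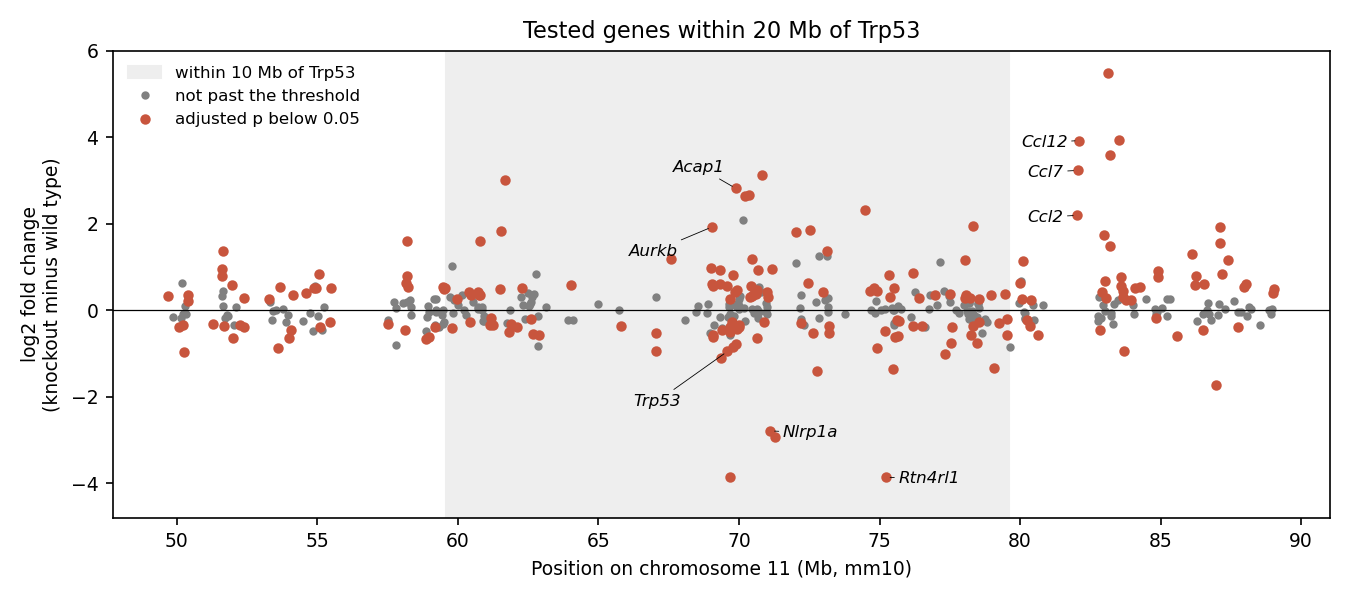
Log2 fold change of tested genes (vertical axis, knockout minus wild type) by position on chromosome 11 in Mb of the mm10 genome (horizontal axis) within 20 Mb of Trp53, with red points past an edgeR adjusted p of 0.05, grey points not past it and the 10 Mb window shaded. In the window 120 of 251 tested genes other than Trp53 are past the threshold, including Rtn4rl1 at -3.86 and Acap1 at 2.82.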

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

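The GC content and length offset was chosen after seeing the data, and the other settings before. No gene called in the main comparison changed sign under any setting that tested it. The counts, 2714 higher and 2379 lower, moved by over 1.5 times with a minimum fold of 1.5 (723 and 261), and the lower count with an adjusted p below 0.01 (1561), as a stricter criterion must. The share of higher calls, 53.3%, was 43.2% with upper-quartile factors (2259 higher, 2965 lower) and 43.1% with the GC and length offset (2388 and 3152), where the median of all genes lay at -0.05, and 61.4% with library size alone (3098 and 1948), where it lay at 0.06. DESeq2 called 2491 and 2269. Leaving out each library gave 2178 to 2578 higher and 1925 to 2279 lower. Same-numbered libraries did not deviate together (correlations -0.00356, -0.0351 and -0.160, against -0.0697 to 0.0999 for pairs with different numbers). A pairing with a small shared effect could give such values too, and the labels do not say whether the numbers pair samples. The replicate block gave 2455 and 2064, with 4476 of 5093 calls kept.

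With an estimated correlation G2/M and mitosis genes had an adjusted p of 0.0575, and 1 secondary list passed instead of 5, against 8 with fry and 12 with its mixed test. Glycolysis made it 6 without wild-type replicate 2 (adjusted p = 0.00735) and without the filter on low counts (adjusted p = 0.0298). Of the marker lists 0 passed, against 2 without the filter on low counts, 6 with fry and 7 with its mixed test. Leaving out a library gave 0 to 1, namely the neutrophil list without wild-type replicate 1 (adjusted p = 0.0378) and the macrophage list without knockout replicate 2 (adjusted p = 0.0403). The odds ratio near Trp53 was 1.23, 1.41 within 5 Mb, 1.21 within 20 Mb and 1.39 without the filter (Fisher's exact p = 0.00297). The cause was not tested. Results not past the threshold changed direction in places. The stress response list pointed down with the GC offset (adjusted p = 0.931), the MHC class II list down without the filter (adjusted p = 0.979) and on leaving out 4 of the libraries in turn (leave-one-out range 0.751 to 0.969), the monocyte list up without the filter (adjusted p = 0.799) and the osteoclast list down without wild-type replicate 3 (adjusted p = 0.979, leave-one-out range 0.751 to 0.994). Tnf had a log2 fold change of -0.051 with upper-quartile factors and of -0.055 to 0.059 on leaving out a library, and Cd79b of -0.27 to 0.091. F13a1 passed without wild-type replicate 1 (adjusted p = 0.00506) or knockout replicate 2 (0.0235), and with 4 other settings. Acta2 passed without wild-type replicate 2 (0.0162) or knockout replicate 3 (0.0439), with limma-voom and with no filter, and Csf1r with library size alone (0.0223). The cause was not tested. At this depth genes such as Il6 and Cxcl1 were too low to pass the filter of the main comparison.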

Other observations

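The gene families, the GC content and length offset, the comparison of nuclear with mitochondrial respiratory genes and the count of changes of 2-fold or more near Trp53 were chosen after seeing the data, and the other tests before. Further families rose in the knockout. All 7 tested guanylate-binding protein genes, interferon-induced GTPases of host defence, rose, with a median log2 fold change of 1.78; Gbp2 went from 8.16 to 28.1 CPM. Of 7 Schlafen genes 6 rose, among them Slfn1 (5.49, from 0.117 to 5.40 CPM) and Slfn9 (1.73). Slfn1 and Slfn9 lie on chromosome 11, 13.5 and 13.4 Mb from Trp53. Of 19 immunoproteasome and MHC class I genes 14 rose (median 0.63), among them Psmb8, Psmb9 and H2-K1 at 0.63, 0.72 and 0.47. Of 8 MS4A genes 6 rose (median 1.22). Of 14 tubulin genes 11 rose (median 0.92), with Tubb5 from 351 to 859 CPM. Of 12 histone genes 9 rose and 2 fell (median 1.41) at low levels; most replication-dependent histone messages lack a poly(A) tail.

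Of 18 vacuolar ATPase genes, which encode the proton pump that acidifies lysosomes, 13 fell and 1 rose, with a median of -0.28 and Atp6v1a from 885 to 546 CPM. The number that fell was 11 to 15 across the scalings and the GC offset. Of 38 proteasome subunit genes 14 rose (median 0.16), of 76 mitochondrial ribosomal protein genes 34 rose (median 0.23), and of 73 cytosolic ribosomal protein genes 26 rose and 2 fell (median 0.18). These 3 counts depended on the scaling, at 11 to 25, 22 to 42 and 17 to 37 higher genes, while the sign of each family's median was the same under every scaling and the offset. All of these lists passed camera of limma at the preset correlation, and none did with an estimated one (adjusted p from 0.143 to 0.699). Since they were chosen after seeing the same data, passing is no independent support.

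The first pattern is the rise of 28 of 30 interferon response genes. Trends with GC content or transcript length are argued against as the whole cause, since the median log2 fold change was 1.09 after their removal and 1.18 before. Of the 28 genes 0 lie within 10 Mb of Trp53, but map positions do not depend on the data and a nearby variant could act on genes elsewhere, so DNA of another strain around Trp53 stays open. The 17 type I interferon genes examined had 2 reads in all 6 libraries together, at 18 h after MCSF was raised. Next to no transcripts of these ligands were thus counted at this depth. Reads that map to several of these genes may have been lost, since their handling is not given. Interferons of other types were not examined. A difference in culture or handling between the genotypes stays open, because the labels give no culture, day or batch, and so do strain differences in the genome and an effect of p53 loss, which the design names but cannot separate from these.

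The second pattern is the fall of mitochondrial genome transcripts. Of 12 tested 10 fell and 0 rose, with a median of -1.02 (camera adjusted p = 6.00e-08 at the preset correlation and 0.143 with an estimated one). mt-Co1 went from 1571 to 854 CPM. The share of all counts was 0.576 ± 0.0874% in wild type and 0.310 ± 0.0385% in the knockout (n = 3, two-sided exact permutation test, p = 0.1, the smallest possible). That share lacks 5 of 13 mitochondrial protein genes, listed at 0 in all libraries, and the tested transcripts include some that encode no protein. After removal of trends with GC content and length the median was -0.95, against such trends as the whole cause. A drop of respiratory chain genes in general is argued against by the nuclear-encoded list, whose median was -0.017. RNA quality, mitochondrial content per cell, shared handling of a genotype's libraries and the genotype itself stay open. The counts cannot separate these.

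The third pattern is a set of large changes near Trp53. Within 5 Mb 16 of 113 tested genes were past the threshold with a change of 2-fold or more (14.2%, against 8.41% elsewhere, odds ratio 1.80, 95% interval 0.983 to 3.08, Fisher's exact p = 0.0395). The interval includes 1 while the p-value lies below 0.05, so the 5 Mb result is borderline. The odds ratio was 1.20 within 10 Mb (Fisher's exact p = 0.361) and 1.12 within 20 Mb (Fisher's exact p = 0.485). Both wider windows hold the genes of the 5 Mb window, so they cannot count against an excess confined to it. The 2-fold limit was chosen after seeing the data, so an excess is neither established nor excluded. Nlrp1a and its neighbour Nlrp1c-ps fell (-2.79 and -2.92), and Acap1 and Scimp rose (2.82 and 3.12). For calls of any size within 10 Mb the odds ratio was 1.23, with an upper limit of 1.59. Without the filter on low counts it was 1.39 (Fisher's exact p = 0.00297). These values neither show nor exclude flanking DNA of another strain. This and an effect of p53 loss therefore cannot be told apart for these genes.

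The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Each of the other 9 sets 2 libraries of one genotype and 1 of the other against the reverse, so it keeps part of the genotype difference and gives no value for libraries without one. The genotype split called 2714 genes higher and 2379 lower, and the highest of the other splits 0 in both, so 1 split reached each count. In the same way 1 split reached the size of the median of the p53 target genes (0.520, highest other 0.207), DNA replication genes (1.20 and 0.462), G2/M and mitosis genes (1.77 and 0.707) and inflammatory genes (0.522 and 0.310). For the number of secondary lists past the threshold, 5 of the 10 splits gave at least 5, and the highest other gave 6, which for the same reason says nothing of how many lists would pass without a genotype difference.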
